A study of Gracilariopsis lemaneiformis with 12 samples.

How the data were processed

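RNA was sequenced from tissue labelled rhizoids of Gracilariopsis lemaneiformis, in 12 libraries that the labels place in 4 groups of 3: untreated controls and samples treated with 100 µM indole-3-acetic acid (IAA), each at day 1 and day 3. All 12 libraries carry the same tissue label, but the series' design text also names branches and can be read as tissue that differed between the days, so a comparison of days may hold a difference of tissue. Per the labels' protocols, tissue was ground in liquid nitrogen, RNA was extracted with a plant column kit and libraries followed standard Illumina protocols. The submitters' processing notes name Bowtie2 2.2.5 without stating its role. The assembler, the quantifier, the annotation and any filter on reads are not given in the sources used here. Nothing states that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

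The expression table deposited by the authors holds FPKM values, fragment numbers scaled to sequence length and library size, per the file headers, with 2 decimals for 30780 assembled sequences. Of these, 23287 have IDs beginning with Unigene. The other 7493 are contigs whose IDs begin with CL, a cluster number and a contig number, and fall into 2479 clusters by that number. Reading the number after CL as a cluster of related contigs follows the form of the ID, which no label explains. The authors also deposited 1 table of changed sequences per day, with a log2 ratio of IAA over control and p-values and q-values, per the file headers. The authors' test is not given in the sources used here. The log2 ratios in the authors' deposited tables are all at least 1 in size and the q-values lie below 0.001. The FPKM values in those tables were identical to the whole table. No file used here pairs an ID with a gene name, a description or a sequence. The 20 gene lists fixed before the data were examined could therefore not be applied, and at most 2 IDs that were higher and 2 that were lower are named per comparison.

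FPKM values carry no read totals. Low Unigene values fell on multiples of the value of 1 read, so the relative depth could be estimated from 2047 Unigene sequences with no value above 5 FPKM and a lowest value above 0 of at least 0.2 FPKM that at least 3 libraries shared within 8%. It ranged from 0.977 to 1.02 over the 12 libraries. In these sequences 1 read was worth a median of 0.269 FPKM, and 73.9% of 10901 values between 1.5 and 10 multiples lay within 0.1 of a whole number, against 20% by chance. For cluster contigs the share was 34.1% of 540 values. Absolute depth is unknown, and no count test was run because whole reads could not be recovered for most sequences.

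FPKM values were analysed as log2(FPKM + 1) for the 14065 sequences with a mean of at least 1 FPKM over all libraries. The other 16715 sequences were left out. One linear model with 4 group means was fitted in limma 3.58.1 (R 4.3.3) with an abundance trend in the variance prior. The tests were two-sided, p-values were adjusted by Benjamini-Hochberg over sequences, and an adjusted p under 0.05 is called a change. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low sequences. The comparisons were IAA against control at day 1 and at day 3, the difference between these effects, and day 3 against day 1 within controls and within IAA. Named IDs had an adjusted p under 0.05, a group mean of at least 5 FPKM and, for pairwise comparisons, no overlap between the libraries of the groups, and were the 2 largest changes in each direction. Simulated data held 14065 sequences with the observed spread and independent normal errors, with 67, 67 and 66 of them changed 1.5-fold, 2-fold and 4-fold. They held far fewer changes than the real data and no error of scaling, so recovery and false calls may not carry over to the real lists. In them the day 1 comparison recovered 47.8% of 1.5-fold, 68.7% of 2-fold and 92.4% of 4-fold changes, with 7 false calls. The day 3 comparison recovered 38.8%, 67.2% and 97.0%, with 6 false calls. The difference between days recovered fewer, 23.9%, 40.3% and 78.8%, with 7 false calls, so a difference not detected there may still exist. Controls over time gave 43.3%, 64.2% and 87.9% with 11 false calls, and IAA over time 50.7%, 70.1% and 90.9% with 4. Depth estimation was checked in a separate simulation of low sequences built from whole reads, where it was within 0.103% of the simulated depth. In that simulation 86.0% of values lay within 0.1 of a whole number, against 73.9% of the real Unigene values. Its accuracy may therefore not carry over to the real libraries.

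Classes of mean abundance, the contig sums per cluster, the kernel densities of log2 ratios (bandwidth 0.1) and the set of sequences lower in day-3 controls were chosen after seeing the data. A mixture of normal curves was tried first for that set and was replaced by the valley of the density because it split the ratios poorly. Densities used ratios within 3 of 0, the set took Unigene sequences with a control ratio between -3 and the valley, and medians of ratios used means plus 0.01 FPKM. FPKM of contigs was added within a cluster and tested with the same model, on the deposited scale only. Overlaps expected within abundance classes were also computed after seeing the data. Rescaling to a common sum multiplied the values about 3-fold before the same pseudocount was added, so it changed the pseudocount's weight as well as the scaling. The alternatives tried were the pseudocount, the filter on low values, 3 rescalings, a replicate block, fits to the compared groups alone, other variance priors, a fold minimum and leaving out each library. Replicate numbers are shared by all groups in the labels, and the check of whether they pair the libraries is given with the alternatives. Designs, alternatives and the naming rule were set before the data were examined unless stated otherwise.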

Results

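Gracilariopsis lemaneiformis is a red seaweed grown for agar, and IAA is the main natural auxin of land plants. The series asked how IAA changes the transcriptome alongside growth and branching, and its libraries cover untreated and IAA-treated tissue at day 1 and day 3, with 3 libraries per group. Summed FPKM per library lay between 291205 and 308835, and relative depth differed by at most a few percent, with day-3 IAA libraries lowest at 0.977 to 0.982. Between 6612 and 7934 of the 30780 assembled sequences were listed at 0 in a library. The number was highest in the day-3 controls, at 7729 to 7934. Pearson's r across the 14065 tested sequences was 0.980 to 0.986 for the 12 pairs of libraries within a group and 0.945 to 0.974 for the 54 pairs between groups. No pair of libraries held identical values. The first principal component carried 45.9% of the variance and separated the day-3 controls from the day-1 libraries, with the day-3 IAA libraries between them. The second carried 15.3% and set the day-3 IAA libraries apart from the rest.

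**Figure D1:**
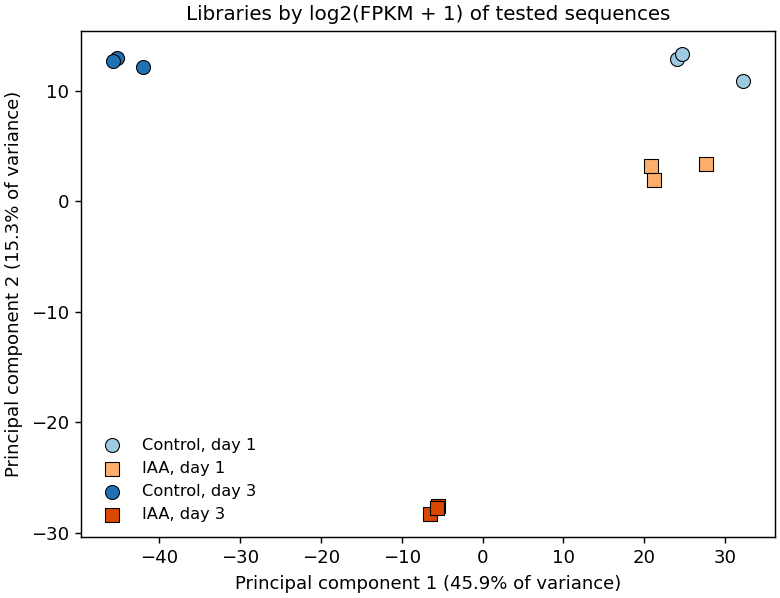
Each point is 1 library, placed by its scores on principal components 1 and 2 of log2(FPKM + 1) over 14065 sequences, with circles for controls and squares for IAA. The day-3 controls lie between -45.7 and -42.0 on the first component and the day-3 IAA libraries between -6.48 and -5.48.

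The first comparison asked what 1 day of IAA changed. Large rises at day 1 were few and were led by contigs of cluster CL389. CL389.Contig4_All went from 0.0833 ± 0.144 FPKM in controls to 21.1 ± 3.77 FPKM with IAA (SD, n = 3), a log2 change of 4.35 ± 0.16 (SE; limma adjusted p = 7.014e-09). CL389.Contig2_All went from 0.677 ± 0.181 to 30.6 ± 6.91 FPKM (log2 change 4.22 ± 0.16, limma adjusted p = 8.221e-09). Summed over its 6 contigs, cluster CL389 rose 1.98-fold, from 78.5 ± 1.93 to 155 ± 1.83 FPKM, so the cluster as a whole moved less than these contigs. The largest falls were in CL1927.Contig14_All, from 20.5 ± 2.89 to 1.09 ± 0.944 FPKM (log2 change -3.48 ± 0.32, limma adjusted p = 1.716e-05), and CL116.Contig2_All, from 8.99 ± 2.38 FPKM to a value listed at 0 in all 3 IAA libraries (limma adjusted p = 2.512e-05). The 7 contigs of CL1927 together fell by 0.21 ± 0.03 on the log2 scale (limma adjusted p = 0.0004815). Those of CL116 together were at 37.1 ± 2.29 and 35.5 ± 0.917 FPKM (limma adjusted p = 0.3371).

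In all, 739 sequences were higher and 1223 lower with IAA at day 1 by limma with Benjamini-Hochberg adjustment, out of 14065. Most changes were small: 97 of those higher and 59 of those lower moved by at least 1 on the log2 scale. Calls were most common among abundant sequences, with 464 higher and 734 lower of the 3381 at 20 FPKM or more. At 1 to 5 FPKM 94 were higher and 128 lower of 7315. Of these, 29 and 13 of the abundant and 30 and 24 of the low ones moved by at least 1 on the log2 scale. The scale understates changes of low sequences, so the difference between classes may reflect detection. When contigs were summed per cluster, 63 loci rose and 39 fell by at least 1 on the log2 scale out of 11044. Of these 11044 loci, 1911 were clusters and the rest were single Unigene sequences, whose values the summing left unchanged. The 63 and 39 were not split by kind. The share of calls that were higher was 37.7% and became 56.1% with median-of-ratios size factors, so the balance of small changes rests on the scaling.

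**Figure D2:**
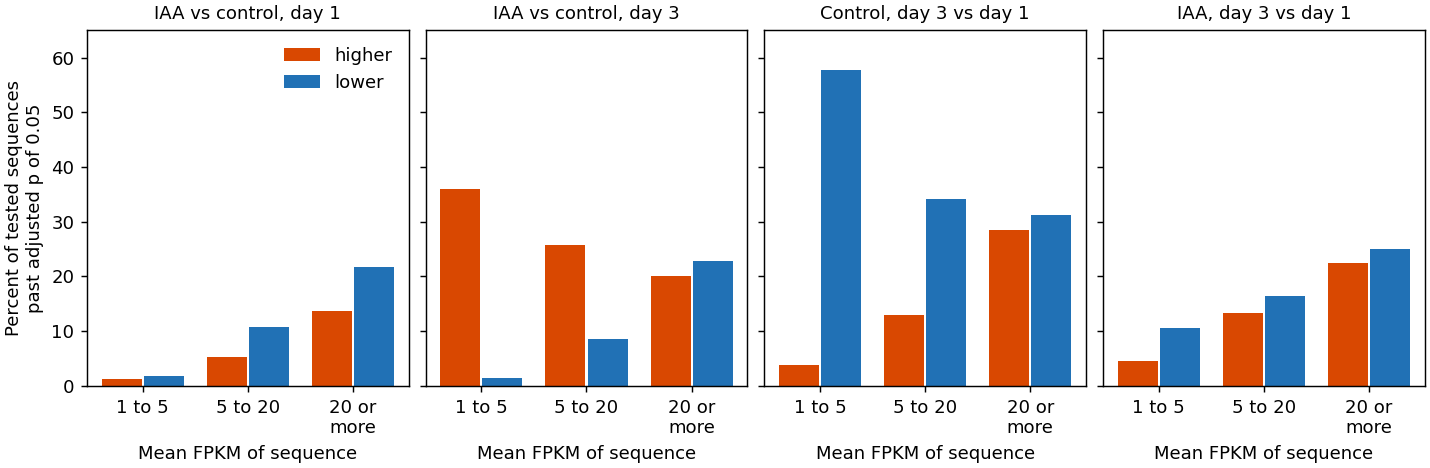
Bars give the percent of tested sequences called higher (orange) or lower (blue) in 4 pairwise comparisons, by mean FPKM over all libraries. In the class of 1 to 5 FPKM, 36.0% were higher with IAA at day 3 and 57.8% were lower in controls at day 3 than at day 1.

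The second comparison asked what IAA changed by day 3. The largest rises were in 2 contigs of cluster CL1644. CL1644.Contig2_All was at 24.4 ± 3.49 FPKM in day-3 controls and 789 ± 11.01 FPKM with IAA (SD, n = 3), a log2 change of 4.97 ± 0.14 (SE; limma adjusted p = 7.994e-10). CL1644.Contig10_All was at 3.42 ± 1.13 and 111 ± 5.92 FPKM (log2 change 4.70 ± 0.22, limma adjusted p = 4.901e-08). The 10 contigs of CL1644 together rose 2.47-fold at day 1, from 134 ± 23.5 to 330 ± 5.37 FPKM, and 17.0-fold at day 3, from 62.4 ± 5.28 to 1061 ± 12.9 FPKM. The rise was larger at day 3 by 2.76 ± 0.14 on the log2 scale (limma interaction adjusted p = 3.254e-08). Cluster CL389 rose 1.90-fold at day 3, from 74.6 ± 0.436 to 142 ± 2.47 FPKM, and its change did not differ detectably between days (interaction -0.06 ± 0.03, limma adjusted p = 0.1366).

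**Figure D3:**
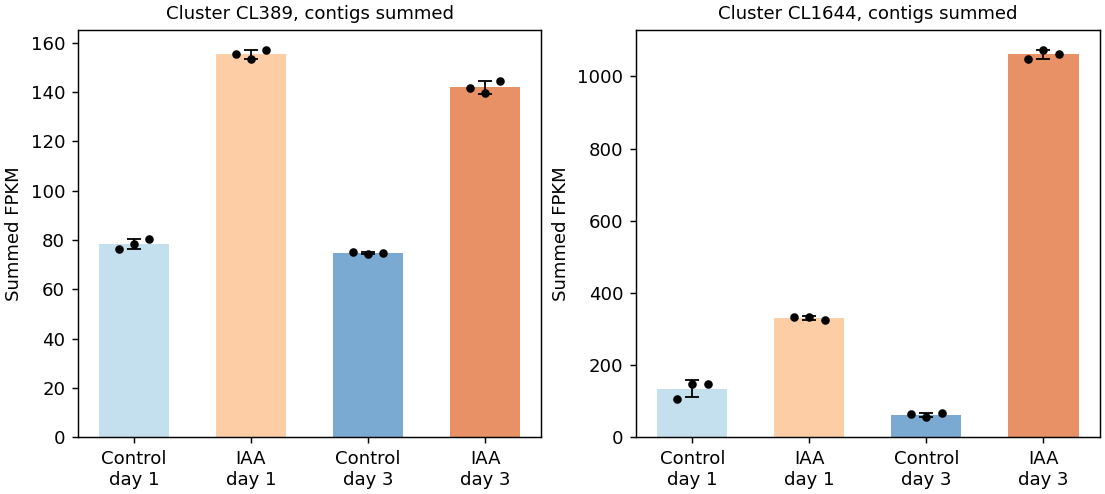
Bars show the mean FPKM summed over the contigs of clusters CL389 (6 contigs) and CL1644 (10 contigs) in each group, with SD as error bars and points for the 3 libraries. CL389 is at 155 and 142 FPKM with IAA on days 1 and 3, while CL1644 reaches 1061 FPKM with IAA at day 3.

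The largest falls at day 3 were in CL717.Contig9_All and Unigene1460_All. CL717.Contig9_All was at 7.13 ± 2.46 FPKM in controls and 0.317 ± 0.548 FPKM with IAA (SD, n = 3; log2 change -2.66 ± 0.66, limma adjusted p = 0.0087). The 7 contigs of CL717 together were at 26.1 ± 0.467 and 25.7 ± 0.476 FPKM (limma adjusted p = 0.6601). Unigene1460_All was at 19.2 ± 3.64 FPKM in controls and 3.54 ± 0.720 FPKM with IAA (log2 change -2.15 ± 0.17, limma adjusted p = 4.326e-06). The same sequence was at 3.41 ± 0.887 FPKM in day-1 controls.

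At day 3, 4178 sequences were higher and 1165 lower with IAA by limma, of which 328 and 47 moved by at least 1 on the log2 scale. As deposited, the rises were mainly of low sequences. This held when scaled to abundant sequences, those of 20 FPKM or more, with 2740 sequences of 1 to 5 FPKM higher and 102 lower. It did not hold after quantile normalization, which gives every library the same distribution and so can remove a shift of a whole class. In the class of 1 to 5 FPKM 2632 of 7315 were higher and 109 lower, with a median log2 change of 0.34. In the class of 20 FPKM or more 680 of 3381 were higher and 770 lower, with a median of -0.03. The higher share of calls was 78.2% as deposited and 82.3% when scaled to abundant sequences. It was 65.9% after rescaling to a common sum, which also made the pseudocount smaller relative to the values. With median-of-ratios size factors it was 49.0%, and after quantile normalization 49.1%. Median-of-ratios and quantile scaling moved the median of all sequences by -0.12 and -0.16, and the median of the low class was 0.26 and 0.04 under them. Quantile normalization left 631 low sequences higher and 534 lower, and median-of-ratios scaling left 328 abundant sequences higher and 2138 lower (median -0.19).

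The third comparison set the IAA effect at day 3 against that at day 1. The effect was more positive at day 3 for 3665 sequences and more negative for 880 by limma's interaction contrast. Of these, 2021 and 88 were in the class of 1 to 5 FPKM, against 373 and 292 after quantile normalization. The higher share, 80.6%, became 48.6% with median-of-ratios size factors and 54.5% after quantile normalization. These scalings moved the median of all sequences by -0.17 and -0.20. The share was 81.1% when scaled to abundant sequences and 71.2% after rescaling to a common sum. By the naming rule, the largest positive differences were in CL557.Contig2_All (5.26 ± 1.84, limma adjusted p = 0.0492) and CL116.Contig2_All (5.06 ± 0.44, limma adjusted p = 1.118e-05). The largest negative differences were in CL557.Contig1_All (-6.11 ± 1.68, limma adjusted p = 0.01776) and Unigene1707_All (-4.85 ± 0.73, limma adjusted p = 0.0005733). With a pseudocount of 0.1 FPKM these differences were 8.59, 11.04, -10.46 and -8.36 in the order given. Their sizes, and the order of the positive ones, thus depend on the pseudocount. The 2 contigs of CL557 moved in opposite directions, and their sum showed no detectable difference (-0.13 ± 0.28, limma adjusted p = 0.7154). The call for CL557.Contig2_All was lost on leaving out any 1 of 9 libraries (limma adjusted p 0.0747 to 0.107), the exceptions being replicate 1 of day-1 IAA, replicate 2 of day-3 controls and replicate 2 of day-3 IAA. Over all alternatives that tested this contig itself, the limma adjusted p ranged from 0.004 to 0.117. Unigene1707_All was at 1.14 ± 1.10 FPKM in controls and 14.04 ± 1.55 FPKM with IAA at day 1, and at 4.85 ± 2.88 and 0.727 ± 1.26 FPKM at day 3 (SD, n = 3).

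Calls at the 2 days use separate libraries. Of the 739 sequences higher at day 1, 266 were higher at day 3, against 219.5 for independent lists over all sequences and 173.7 for independent lists within the 3 abundance classes. Of the 1223 lower at day 1, 272 were lower at day 3, against 101 and 199.7. Day-1 calls and day-3 falls were more common among abundant sequences and day-3 rises among low ones, so the class values lie below the first for shared rises and above it for shared falls. Opposite calls numbered 170 for rises followed by falls, against 61.2 and 122.4, and 310 for falls followed by rises, against 363 and 286.5. With no filter on low values the last number was 234, against 127.8 for independent lists over all 30780 sequences. The lists were shorter there although more sequences were counted, which by itself lowers the value for independent lists. Every combination of directions exceeded it, and it was not computed within abundance classes, so this excess has no clear reading. After summing contigs, 35 of the 63 loci that rose by at least 1 on the log2 scale at day 1 did so at day 3, against 1.46 for independent lists. For large falls the number was 3 of 39, against 0.0918. Across all sequences the fold changes of the 2 days were almost unrelated (Pearson's r 0.0954, Spearman's rho -0.0696), where sequences are not independent replicates.

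The time comparisons asked what changed in untreated tissue and in IAA-treated tissue between the days, which may also differ in the tissue taken. In controls 1674 sequences were higher and 6435 lower at day 3 by limma. The falls were mostly of low sequences: 4226 of 7315 in the class of 1 to 5 FPKM, with a median log2 change of -0.56, and 1055 of 3381 at 20 FPKM or more, where 963 were higher and the median was -0.01. With IAA 1545 were higher and 2172 lower, and the median of the low class was -0.11. The median of the low class in controls was -0.55 when scaled to abundant sequences, -0.39 with median-of-ratios size factors and -0.11 after quantile normalization, which left 938 higher and 1281 lower. The median of the abundant class was 0.28 with size factors, which left 2624 higher and 274 lower. The higher share of calls in controls, 20.6%, became 50.6% with median-of-ratios size factors and 48.6% after quantile normalization. These scalings moved the median of all sequences in controls by 0.24 and 0.21. When scaled to abundant sequences the share in controls was 21.5%. The share with IAA, 41.6%, became 59.4% with size factors.

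Of the 6435 sequences lower at day 3 in controls, 1535 were also lower at day 3 with IAA and 241 were higher, against 994 lower for independent lists and 898.7 within abundance classes. Their median log2 change was -0.70 in controls and -0.15 with IAA. These sequences were picked for their fall in controls, so part of that gap would arise without any effect of IAA. Over all tested sequences the medians were -0.24 in controls and -0.06 with IAA. Of the 1674 higher in controls, 762 were also higher with IAA, against 184 and 287.1. The ratios of group means among Unigene sequences of 5 to 20 FPKM fell into 2 peaks in controls, near -1.27 and -0.08 on the log2 scale, with a valley at -0.77 and 32.3% of 1528 sequences below it. The other classes had 1 peak each in controls and no valley, at -1.16 for 1 to 2 FPKM, -1.21 for 2 to 5 FPKM and -0.005 for 20 FPKM or more. With IAA the class of 5 to 20 FPKM had 1 peak, at -0.08. In that class the ratio of IAA to control had 1 peak at day 1, at -0.13, and 2 at day 3, at -0.02 and 0.92.

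**Figure D4:**
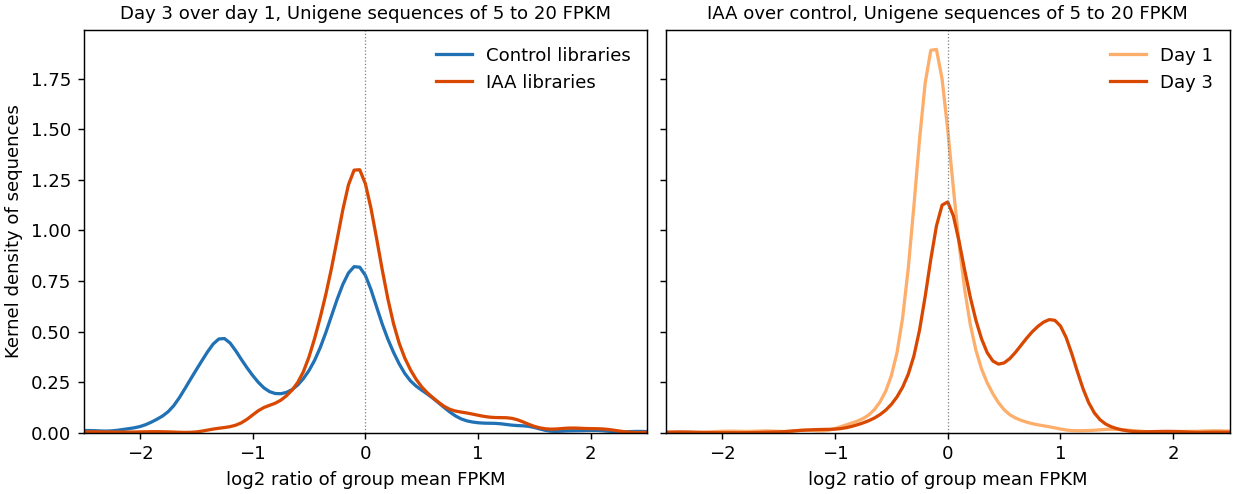
Curves give the kernel density of log2 ratios of group mean FPKM over Unigene sequences with a mean of 5 to 20 FPKM, for day 3 over day 1 (left) and IAA over control (right). Controls show a second peak near -1.27 between days, and IAA over control shows a second peak near 0.92 at day 3 but not at day 1.

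The Unigene sequences below that valley and at 1 FPKM or more numbered 4563 of 9133. Of these, 3946 were at 1 to 5 FPKM, where the densities showed no valley, so the limit there was carried over from the class of 5 to 20 FPKM. They were chosen on the control libraries, so their values in controls and for IAA against control on both days are not independent evidence. Together they took 8.12 ± 0.470% of summed FPKM in day-1 controls, 7.25 ± 0.255% with IAA at day 1, 3.40 ± 0.0886% in day-3 controls and 5.75 ± 0.0675% with IAA at day 3 (SD, n = 3). Their median log2 ratio between days in controls was -1.24 at 1 to 5 FPKM, -1.28 at 5 to 20 FPKM and -1.43 at 20 FPKM or more. In the IAA libraries, which entered the choice through the mean abundance but not through the ratio, the medians were -0.24, -0.25 and -0.38. The other Unigene sequences had medians of -0.03, 0.02 and 0.002 there.

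Among single sequences in controls, CL298.Contig1_All was listed at 0 in all day-1 libraries and at 40.4 ± 1.28 FPKM at day 3 (SD, n = 3; limma adjusted p = 3.509e-07), and CL557.Contig1_All went from 4.02 ± 6.96 to 25.4 ± 2.33 FPKM (limma adjusted p = 0.0265). The latter was listed at 0 in day-1 replicates 1 and 2 and at 12.05 FPKM in replicate 3, and its call was lost without any 1 of the control libraries (limma adjusted p 0.0555 to 0.0967) except that replicate. CL116.Contig2_All and CL1997.Contig2_All were at 8.99 ± 2.38 and 8.18 ± 2.31 FPKM at day 1 and were listed at 0 at day 3 (limma adjusted p = 8.222e-06 and 3.476e-08). The 3 contigs of CL1997 together fell by 0.93 ± 0.04 on the log2 scale in controls. The 6 of CL298 together rose by 0.24 ± 0.03, and both values are on the deposited scale. Median-of-ratios scaling moved the median of all sequences up by 0.24, toward a larger rise of CL298 and a smaller fall of CL1997. The sums were not tested under that scaling. With IAA, CL298.Contig1_All went from 0.680 ± 1.18 to 27.8 ± 4.59 FPKM (limma adjusted p = 3.728e-06) and CL28.Contig4_All from 0.527 ± 0.912 to 21.0 ± 4.66 FPKM (limma adjusted p = 1.079e-05). Summed over contigs, CL298 differed by 0.08 ± 0.03 on the log2 scale (limma adjusted p = 0.05617) and CL28 rose by 0.20 ± 0.06 (limma adjusted p = 0.02458). Unigene1707_All fell from 14.04 ± 1.55 to 0.727 ± 1.26 FPKM (limma adjusted p = 0.0006027). CL40.Contig2_All went from 8.77 ± 1.16 FPKM to values listed at 0 (limma adjusted p = 3.115e-05), and the 2 contigs of CL40 together fell by 0.79 ± 0.07 on the log2 scale.

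The authors' deposited tables list 421 sequences higher and 415 lower with IAA at day 1, and 1945 higher and 362 lower at day 3. Of the 836 at day 1, 351 passed the filter on low values and 207 of these were called here in the same direction. Of the 2307 at day 3, 1493 passed the filter and 1362 were called in the same direction. No sequence was called in the opposite direction on either day. A further 1755 sequences at day 1 and 3981 at day 3 were called here and are not in the authors' deposited tables, which hold no change below 1 on the log2 scale.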

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

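The interaction contrast was set before the data were examined, and the other tests below were chosen after the results they bear on were seen. The effect of IAA differed between days, by limma's interaction contrast, for 4545 sequences and for 6 of the IDs named in the IAA comparisons. Of 100 drawn divisions of the libraries into treated and control within each day, the real one included, 1 gave as many calls. The divisions stand for no IAA effect on either day, not for an equal effect on both. They therefore cannot exclude chance for a difference between days. The highest other division gave 2845 calls and kept the real groups at day 3, so much of the count follows the day-3 groups. The log2 effect at day 3 minus that at day 1 was 3.42 in CL1644.Contig2_All, 2.99 in CL1644.Contig10_All, -0.71 in CL389.Contig2_All and -1.67 in Unigene1460_All. It was 3.67 in CL1927.Contig14_All and 5.06 in CL116.Contig2_All, while the sums of those clusters differed by 0.05 ± 0.04 and 0.11 ± 0.06 (limma adjusted p = 0.3426 and 0.15).

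Low sequences as a class were lower in day-3 controls than in day-1 controls and in day-3 IAA libraries. The authors' scaling to library size would move all sequences of a library by 1 factor, yet the median changes of abundant and low sequences between control days differed by 0.5508 on the log2 scale, which argues against it as the whole cause. A source of fixed composition, such as genomic DNA, would change its sequences by 1 ratio. In the IAA libraries the chosen sequences of 5 to 20 FPKM varied by 0.284 beyond replicate noise (95% bootstrap interval 0.245 to 0.322). Other Unigene sequences of that class varied by 0.292 (0.254 to 0.34). The spread argues against such a source as the only origin of the chosen sequences' reads. It cannot exclude one that gave part of the reads or part of the set. RNA of another organism with regulation of its own may account for the pattern. The chosen sequences also lay below other sequences of 5 to 20 FPKM between days in the IAA libraries, by a difference of -0.2648. Changes between days in controls and with IAA were correlated across all sequences (Pearson's r 0.470). Sequences chosen for a fall in controls would thus lie lower with IAA under any cause shared by both, so the difference does not favour another organism. A response of the alga to time in culture that IAA reduced stays open as untested. So does tissue that differed between days, for the control change alone, and so does a source of fixed composition for part of the reads. These explanations and RNA of another organism cannot be told apart. The sources used here do not give the origin of a sequence, which would bear on another organism only. If tissue differed, it differed together with the day, so the design cannot separate it from time in culture.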

How the results depend on the processing

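The alternatives with a filter at 20 FPKM, scaling to abundant sequences, Unigene sequences alone and contigs summed per cluster were chosen after seeing the data, as was the test on other splits, and the causes of the shifts were not tested except where fewer sequences entered. Requiring a log2 change of at least 1 left 156 calls for IAA at day 1, 375 at day 3, 825 for the difference between days, 1353 for controls over time and 398 for IAA over time. It left 45 sequences higher and 4 lower on both days, and 368 shared with the authors' deposited table at day 3. With fewer sequences tested, a mean of at least 5 FPKM gave 2607 calls for IAA at day 3, 2500 for the difference and 3556 for controls over time. A mean of at least 20 FPKM gave 1528, 1429 and 2067, and 1812 for IAA over time. Quantile normalization gave 2816 for the difference. The other settings kept each count within 1.5 times its value. Leaving out each library gave 1576 to 1754 calls at day 1, 4377 to 4632 at day 3, 3894 to 4298 for the difference, 7175 to 7646 for controls over time and 2938 to 3215 for IAA over time. Named sequences kept their direction and call in 389 fits, lost the call in 29, mostly CL557.Contig2_All, and reversed in 1: the 2 contigs of CL557 summed had a difference of -0.13 (limma adjusted p = 0.7154) where CL557.Contig2_All alone had 5.26, since the sum holds both contigs. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.0587 and 0.0604, against -0.0732 to 0.0653 for other numbers. A replicate block over all libraries gave 1786, 5071, 4231, 7945 and 3507 calls in the order above, and a block within day gave 1788, 4941, 4117, 6378 and 2531. Tests on gene lists and on counts were not run, for want of names and of read counts. Depth limits the low Unigene sequences examined: at a median of 0.269 FPKM per read, a value near 1 FPKM in them rests on few reads. Only sequences with a lowest value above 0 of at least 0.2 FPKM were examined, so 1 read may be worth less in others. Each pairwise comparison allows only 10 splits of its 6 libraries, too few for a share under 0.05. The real splits gave 1962, 5343, 8109 and 3717 calls for IAA at day 1, IAA at day 3, controls over time and IAA over time, and the highest other splits gave 1, 0, 1 and 3. In each case 1 split, the real one, gave as many.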

Other observations

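The test of replicate deviations below was set before its result was seen, and the test on the authors' q-values after. Large rises lasted in part: of the 63 loci that rose by at least 1 on the log2 scale with IAA at day 1, 45 were called higher at day 3, with a median of 1.38 at day 1 and 1.12 at day 3. Of the 39 loci with large falls at day 1, 9 were called lower at day 3, and their median went from -1.30 to 0.06. The interaction contrast was past the threshold, in either direction, for 54 of the 63 and 36 of the 39. Over all 11044 loci it was more positive at day 3 for 3907 and more negative for 846. At day 3, 4290 of all loci were called higher and 1209 lower. The contrast also uses the day-1 libraries that picked the loci. These loci were picked for their size at day 1, so part of the decline would arise without any change.

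Several of the largest single-contig changes, such as CL116 at day 1, CL717 at day 3 and CL557 in the difference between days, were not detectable once the contigs of the cluster were summed. Reads divided differently between similar contigs in each library may cause this, and would make contigs of a cluster deviate in opposite directions between replicates. Over 707 pairs of contigs of 1 cluster with at least 1 large call, the median correlation of replicate deviations was -0.0514, below the range of -0.0257 to 0.0394 that held 95% of 200 random pairings but between the bounds of -0.1 and -0.05 set beforehand for and against it. Over all 7520 pairs the median was -0.153. The explanation stays open for these contigs, as does a change in which transcript of a locus is used, which was not tested.

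In the authors' deposited tables, the IAA and control libraries overlapped for 486 of 836 sequences at day 1 and 510 of 2307 at day 3. Separation of 3 from 3 libraries arises by chance in 10% of sequences. Of those with a log10 q below -10, 35.7% of 1588 overlapped (285 of 549 at day 1 and 282 of 1039 at day 3). This is consistent with a test that did not use the spread between replicates, which is a hypothesis because the authors' test is not given in the sources used here. Overlap was more common among cluster contigs than Unigene sequences, at 66.4% of 599 against 37.1% of 237 at day 1 and 52.7% of 828 against 5.003% of 1479 at day 3 (Fisher's exact test, two-sided, p = 1.359e-14 and 7.804e-155). Sequences are not independent replicates in these tests. Overlap at day 3 also differed by direction, at 14.8% of the 1945 higher and 61.3% of the 362 lower sequences. At day 1 it was 55.3% of the 421 higher and 61.0% of the 415 lower. Kind of sequence and direction were not separated, so the difference between kinds at day 3 may partly follow direction.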
